A study of Caenorhabditis elegans with 12 samples.

How the data were processed

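Small RNA was sequenced from whole Caenorhabditis elegans of the wild-type strain N2 and of mutants carrying mir-71(n4115), a deletion allele of the microRNA gene mir-71, at day 0 and day 5 of adulthood. Worms were grown at 20 °C and placed, soon after the last moult, on plates with 0.1 mg/mL 5-fluorodeoxyuridine, an inhibitor of DNA synthesis that prevents progeny from developing. Each of the 4 groups had 3 libraries, described by the submitters as biological replicates, and groups and replicate numbers were taken from the sample titles.

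Per the submitters' processing notes, the reads were aligned with STAR 2.4.0h, DESeq2 was used and the genome build was WBcel235. Read trimming, the counting rules and the microRNA release are not given in the sources used here. The authors deposited a table of normalised read counts, a signal that is never negative, for 213 mature microRNAs in the 12 libraries. In each library of that deposited table, 100% of the values lay within 0.001 of a whole multiple of one step, which was taken as the normalised value of 1 read. This reading rests on the values alone, since the table holds too few low values for a formal check of it, and read numbers, floors and count intervals given here depend on it. Read numbers obtained by dividing by that step came to between 917170 and 4070663 per library. The deposited values were left as the authors scaled them, and the features behind their size factors are not given in the sources used here. The authors also deposited a log2 version of the table, whose transformation is not stated and which was used only as an alternative.

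For the main tests, 1 was added to the normalised values and log2 was taken. A filter at a mean of 5 over the 12 libraries removed 0 microRNAs, the lowest mean being 5.65. The 4 group means were fitted together in limma 3.58.1 (R 4.3.3) with an intensity trend in the prior variance, which left 8 residual degrees of freedom before moderation. Tests were two-sided, and a change was called at a Benjamini-Hochberg adjusted p under 0.05 over the 213 microRNAs. The 2 mir-71 products were left out of the counts for comparisons between strains and for the difference between the age effects, so that those counts cover 211 microRNAs. Fold changes are on the log2(value + 1) scale, which understates changes of scarce microRNAs, and their errors are limma standard errors. Because these are sequencing reads without molecular identifiers, count intervals and floors cover counting error only.

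Before the data were examined, the design, the gene lists, the alternatives and a rule for the microRNAs to be named were fixed. In each comparison the rule took mir-71, the 8 largest rises and the 8 largest falls past the threshold with a mean of at least 20 and no overlap between the 3 and 3 values, the members of a lifespan list, and the 5 most abundant microRNAs. Examples from other lists were to be the members with the highest and the lowest change, and microRNAs named beyond this rule are said to be chosen after their values were seen. The lists were the let-7, mir-35, mir-51, mir-58, mir-64, lin-4, mir-2, mir-44 and mir-72 families, lifespan microRNAs, mirtrons, nervous-system microRNAs, 1 marker each for muscle, intestine and glia, and the passenger strands. A gene with both arms measured entered a list through its more abundant arm, and the 62 less abundant arms formed the passenger list. By this rule the mir-35 list held miR-41-5p and the lifespan list miR-239a-3p, which are not the arms usually named as guides. The mir-58 list held miR-58b-5p, the only measured arm of its gene, while its other members were 3p arms. Lists with at least 3 members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in limma. camera compares a list with the other microRNAs, so its direction can differ from the sign of the list's own median.

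Totals were compared with a two-sided exact permutation test. Alternatives covered the pseudocount, the filter, 4 other scalings (equal totals, equal totals over the microRNAs left after removing mir-71 and the 5 most abundant, trimmed mean of M-values, and library medians), the deposited log2 values, fits of the compared groups alone, a replicate block, other limma settings, and leaving out each library in turn. Arm ratios, list tests under other scalings and a fit without miR-45-3p, whose values equal those of miR-44-3p in every library so that reads of these copies cannot be separated, were added after the data were seen. Positions are those of the annotated precursor genes in the Ensembl annotation of WBcel235, to which 208 of the 213 microRNAs were matched by name.

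The procedure was tested on simulated data for all 12 libraries and all 213 microRNAs, in 20 runs with 40 changed microRNAs each. Means and spreads were taken from all 12 libraries, and the changes were placed in N2 at day 5. Values were drawn independently for each microRNA, without shifts shared across a library, so the shares of false calls need not hold for these data. It called 16.8% of simulated log2 changes of 1, 58.9% of changes of 2 and 87.7% of changes of 3, and 0.636% of unchanged microRNAs. In separate simulated runs without the 40 changes, camera at an unadjusted p under 0.05 found 100% of lists shifted by 2. It also called 10% of lists that were not shifted.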

Results

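Small RNA libraries were compared between wild-type N2 worms and mir-71 deletion mutants at day 0 and day 5 of adulthood, with 3 libraries in each of the 4 groups. The question was which microRNAs change as adults age and how the loss of mir-71, a microRNA that promotes long life, alters them. The read numbers obtained over the measured microRNAs ran from 917170 in replicate 2 of the mutants at day 0 to 4070663 in replicate 1 of the mutants at day 5. miR-58-3p, the most abundant microRNA and a member of the bantam-related mir-58 family, made up 17.9% ± 6.04 of the N2 total and 20.1% ± 3.87 of the mutant total at day 5 (SD, n = 3 in each group). The library medians of the normalised counts still ran from 77.1 to 290 after the authors' scaling, so that libraries differed in overall level.

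mir-71 lies on chromosome I at 9379927 to 9380020 of WBcel235, on the minus strand, in an intron of ppfr-1, which is transcribed from the same strand. Its guide strand, miR-71-5p, stood at 150855 ± 25401 normalised reads in N2 at day 0 and at 114533 ± 26448 at day 5 (SD, n = 3 in each group). In the mutants it stood at 100 ± 44.0 at day 0 and 153 ± 44.3 at day 5, and the mean over the mutant libraries was 0.0954% of the N2 mean. The log2 difference between mutants and N2 was −10.64 ± 0.43 at day 0 (SE, limma adjusted p = 7.83e-12) and −9.56 ± 0.43 at day 5 (adjusted p = 4.11e-11). miR-71-3p, the passenger strand, stood at 298 ± 126 and 299 ± 110 in N2 at day 0 and day 5, and 0 reads were found in each of the 6 mutant libraries. Against a floor of 3 reads per library, the mutant level was at least 71.3-fold lower at day 0 and at least 80.8-fold lower at day 5. Each of the 12 libraries had the mir-71 level that its label calls for. With age, neither strand passed the test in N2, with log2 changes of −0.41 ± 0.43 for miR-71-5p (limma adjusted p = 0.525) and 0.05 ± 0.49 for miR-71-3p (adjusted p = 0.957), and the sign of both depended on the scaling.

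**Figure D1:**
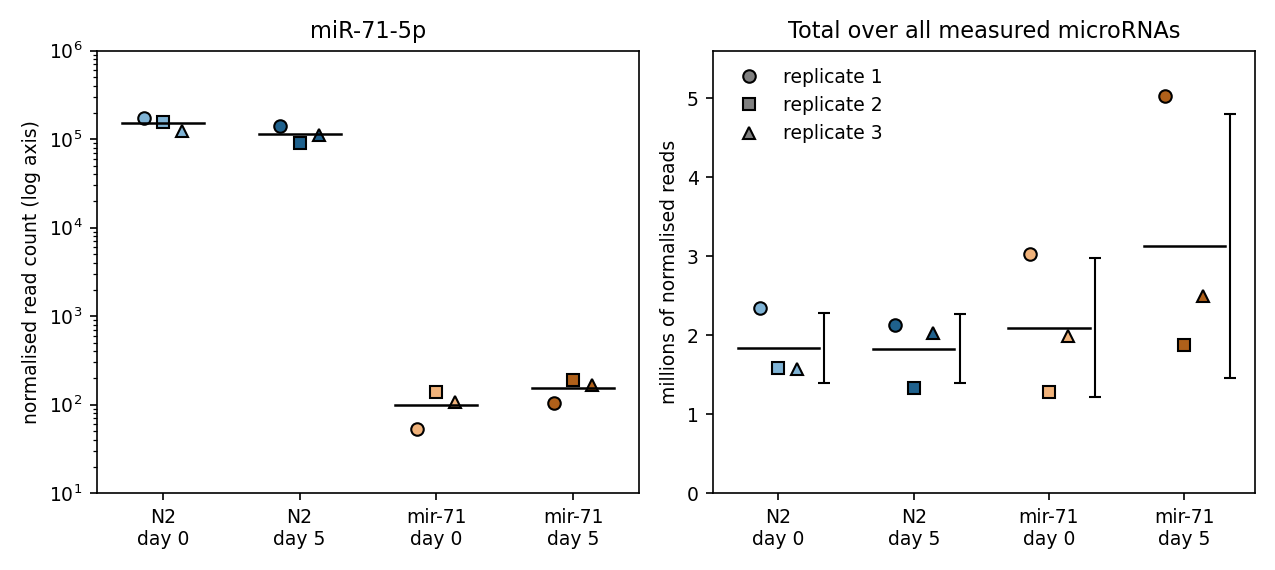
Normalised read count of miR-71-5p on a log axis (left) and total normalised reads over the measured microRNAs (right) in each library, with symbols for replicates, horizontal lines for group means and, on the right, bars for 1 SD (n = 3). miR-71-5p was at most 189 in the mutants and at least 90221 in N2, and the highest total, 5021422, was in replicate 1 of the mutants at day 5.

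The total normalised signal was 1834200 ± 440472 in N2 at day 0 and 1830930 ± 430938 at day 5, and 2095150 ± 879346 in the mutants at day 0 and 3128590 ± 1668630 at day 5 (SD, n = 3 in each group). These totals follow the authors' scaling, which can remove part of a change in the amount of microRNA in the worms. Tests on them therefore cannot show whether that amount changed or stayed the same. Exact permutation tests gave p = 1 for age in N2, p = 0.5 for age in the mutants, p = 0.7 between strains at day 0 and p = 0.3 between strains at day 5, with 0.1 the smallest p that 3 against 3 libraries allow.

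Between day 0 and day 5 in N2, members of the mir-35 family rose, while let-7, 2 of its 6 measured relatives and many scarcer microRNAs fell. The mir-35 family acts in the germline and early embryo and is needed for embryonic development. Its member miR-38-3p went from 136 ± 152 to 2101 ± 1055 normalised reads (SD, n = 3 in each group), a log2 change of 4.55 ± 1.10 (SE, limma adjusted p = 0.0109). The far more abundant miR-39-3p went from 16675 ± 12377 to 68906 ± 20733 reads (2.28 ± 0.76, adjusted p = 0.0418) and miR-35-3p from 22948 ± 16229 to 82740 ± 18825 (2.06 ± 0.71, adjusted p = 0.0456). miR-34-5p, a conserved microRNA studied in stress responses and ageing, rose from 456 ± 172 to 1409 ± 626 reads (1.61 ± 0.50, adjusted p = 0.0348). In all, limma called 50 microRNAs, 16 higher and 34 lower at day 5, and 87 had an unadjusted p under 0.05.

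Other large rises in N2 were those of miR-2214-3p (3.32), miR-2209a-3p (2.44), the passenger strand miR-35-5p (2.35) and miR-4807 (2.09). miR-2208a-5p, with 2 reads over the 3 libraries of N2 at day 0 and 163 at day 5, was called higher, and the ratio of its normalised reads was 50.6 with a 95% counting interval of 13.8 to 422. The largest falls were those of miR-237-3p (−2.71), miR-230-3p (−2.70), miR-357-3p (−2.52), miR-1817 (−2.28), miR-230-5p (−2.28), miR-799 (−2.10), miR-54-5p (−2.09) and miR-788-3p (−2.08). miR-230-3p, from a gene on chromosome X at 5803892 to 5803989 between protein-coding genes, went from 665 ± 109 to 106 ± 44.2 reads (SD, n = 3 in each group), and both arms of its precursor fell. Of the other most abundant microRNAs, miR-58-3p (0.66 ± 0.54), miR-70-3p (−0.88 ± 0.59), miR-80-3p (−0.23 ± 0.51), miR-48-5p (0.38 ± 0.49) and the muscle microRNA miR-1-3p (−1.21 ± 0.65) did not pass the test.

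Among the families, 4 of the 8 measured mir-35 members rose in N2 and 0 fell (5 when adjusted over the list alone, and 7 of 8 under each of the 4 other scalings), with a median log2 change of 1.85 against −0.51 for the other microRNAs. The count was 0 without replicate 2 of N2 at day 0, and 1, miR-38-3p, without replicate 3 of N2 at day 0 or at day 5. The family's cluster lies on chromosome II, with mir-35 at 11537608 to 11537704 on the plus strand, in an intron of Y62F5A.9, which is on the opposite strand. camera called the list higher than the other microRNAs (limma, adjusted p = 5.97e-05), and the adjusted p was 0.985 with an estimated correlation. In the let-7 family, which times larval development, 3 of 7 members fell and 0 rose (3 when adjusted over the list alone). These were miR-241-5p (−1.69 ± 0.40), the lowest of the list, and, chosen after their values were seen, let-7-5p (−1.66 ± 0.43) and miR-795-5p (−1.15 ± 0.39), which was not called with the trimmed mean of M-values and with library medians. Without replicate 2 of N2 at day 0 or at day 5 the count of members that fell was 0. The highest of that list, miR-48-5p, did not pass. In the lin-4 family, also of developmental timing, miR-237-5p fell by 1.73 ± 0.44 and lin-4-5p had −0.88 ± 0.39 (adjusted p = 0.108), and both passed when adjusted over the list alone.

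Of the nervous-system microRNAs, 2 of 5 fell in N2 and 0 rose (2 fell when adjusted over the list alone, and 0 to 3 fell with 1 library left out). They were lsy-6, which sets the left-right asymmetry of a pair of taste neurons (−2.08 ± 0.71), and, chosen after its value was seen, miR-790-5p (−1.48 ± 0.42). In the mir-58 family, 2 of 7 measured members rose, miR-2209c-3p (3.17 ± 0.76) and miR-2209a-3p, both scarce, while the list's median was −0.06 (0.36 with the trimmed mean of M-values and 0.48 with library medians) and its mean 0.73. Of the 3 measured mirtrons, a class made from spliced introns, miR-1018, annotated between protein-coding genes and not in an intron of one, rose by 2.35 ± 0.70. In the same list miR-1020-3p, chosen after its value was seen, fell by 1.42 ± 0.49 (3 passed when adjusted over the list alone). Among the 61 passenger strands, 4 rose and 12 fell (5 and 13 when adjusted over the list alone). With 1 library left out, 1 to 6 rose and 2 to 18 fell. Of the 8 measured lifespan microRNAs apart from mir-71, 1 rose, miR-34-5p. The values of miR-238-3p (0.46 ± 0.41), miR-239a-3p (−0.42 ± 0.50), miR-239b-5p (4 reads against 1, ratio 2.48, counting interval 0.246 to 122), miR-246-3p (0.86 ± 0.54) and miR-228-5p, which is also the glial marker (−0.55 ± 0.50), did not pass. No member of the mir-51, mir-64, mir-2, mir-44 and mir-72 families passed in N2 under the authors' scaling, alone or adjusted over the list, nor did the muscle marker and the intestinal marker miR-60-3p (−0.82).

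**Figure D2:**
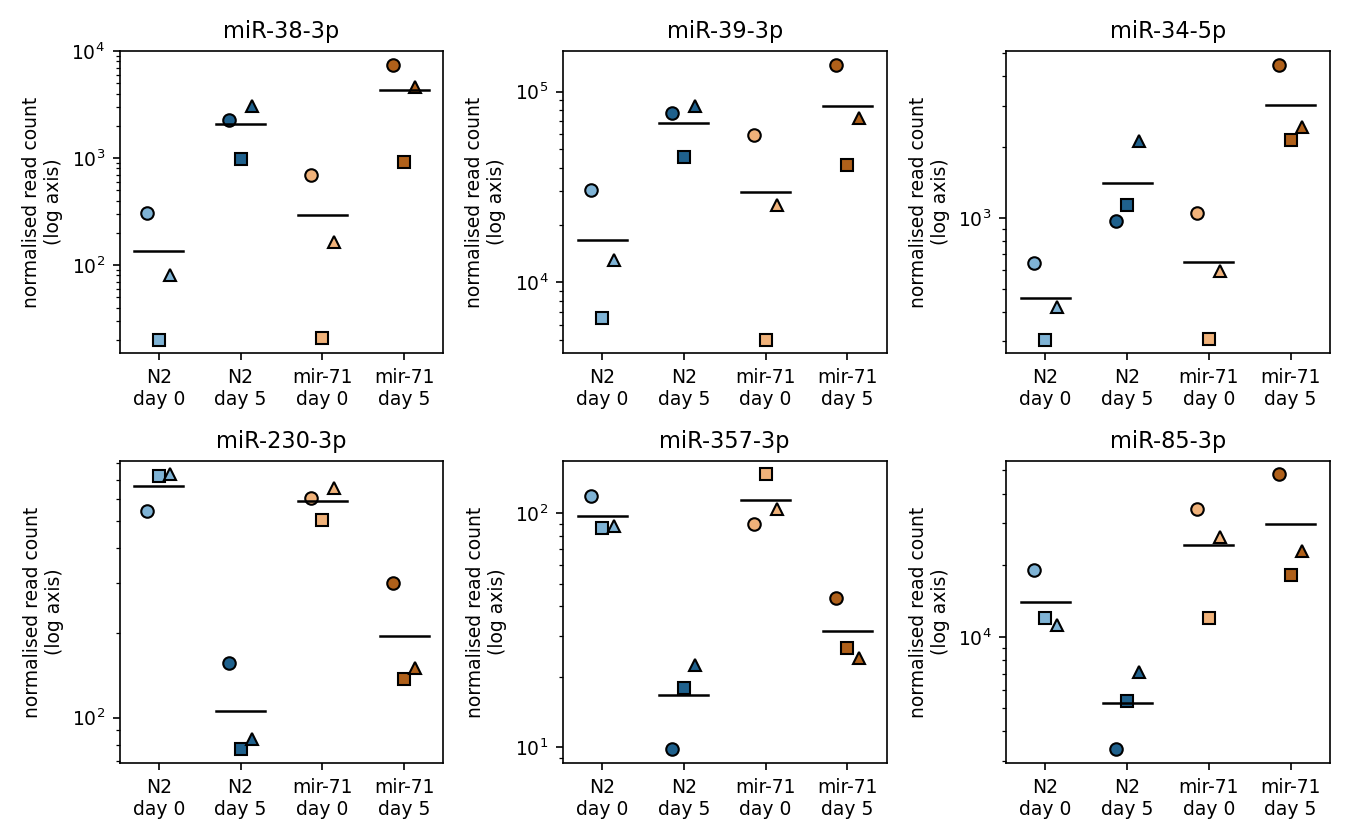
Normalised read counts, on log axes, of 6 microRNAs in each of the 12 libraries, with symbols for replicates as in the plot of miR-71-5p and lines for group means. miR-38-3p, miR-39-3p and miR-34-5p lay higher at day 5 than at day 0 in N2, miR-230-3p and miR-357-3p lay lower at day 5 in both strains, and miR-85-3p lay higher in the mutants than in N2 at day 5.

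The median log2 change with age in N2 was −0.48, and the trimmed mean of M-values and the library medians moved it by 0.39 and 0.54. Under these 2 scalings the calls were 37 higher and 40 lower, and 42 higher and 34 lower, and 48 of the 50 microRNAs, 16 higher and 32 lower, were called in the same direction under all 4 other scalings. Relative to the median change, miR-38-3p had 5.03, miR-34-5p 2.09, let-7-5p −1.17 and miR-230-3p −2.22. The count depended on single libraries: it was 10 without replicate 2 of N2 at day 0, 26 without replicate 3 of N2 at day 0 and 22 without replicate 2 of N2 at day 5. Whichever of the 12 libraries was left out, miR-2208a-5p, miR-2214-3p, miR-2209a-3p, miR-237-3p, miR-230-3p, miR-357-3p, miR-1817 and miR-230-5p were called, and of the 17 named microRNAs past the threshold the other 9 lost the call at least once.

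In mir-71 mutants, miR-38-3p had the largest rise between day 0 and day 5, and miR-34-5p rose as well. miR-38-3p went from 291 ± 353 to 4341 ± 3293 normalised reads (SD, n = 3 in each group), a log2 change of 4.55 ± 1.10 (SE, limma adjusted p = 0.0125). miR-34-5p went from 648 ± 374 to 3016 ± 1276 reads (2.31 ± 0.50, adjusted p = 0.0096). miR-238-3p, whose loss shortens life, went from 45281 ± 8274 to 124334 ± 45082 reads (1.41 ± 0.41, adjusted p = 0.0318). Both arms of mir-230 and miR-357-3p fell, with miR-230-5p going from 335 ± 67.1 to 81.8 ± 37.2 reads (−2.09 ± 0.42, adjusted p = 0.00821). limma called 29 microRNAs, 21 higher and 8 lower at day 5, and 65 had an unadjusted p under 0.05.

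Other large rises in the mutants were those of miR-2208a-5p (4.32), miR-4922 (4.04), miR-2214-3p (3.49), miR-239a-5p (2.80), miR-243-5p (2.63) and miR-355 (2.12). The 8 falls were those of miR-36-5p (−2.33), miR-51-3p (−2.27), miR-230-5p, miR-1830-3p (−2.04), miR-357-3p (−1.84), miR-1817 (−1.78), miR-230-3p (−1.66) and miR-1819-3p (−1.41). Of the 8 lifespan microRNAs, 3 rose and 0 fell (4 when adjusted over the list alone), namely miR-34-5p, miR-238-3p and miR-239b-5p (2.82 ± 0.81), the last at a mean of 2.26 ± 1.97 reads at day 0. With 1 library left out, 1 to 4 rose, and miR-239b-5p lost its call under at least 1 of the 4 other scalings. lin-4-5p (0.09), miR-239a-3p (−0.10), miR-246-3p (1.53), miR-80-3p (0.68) and miR-228-5p (0.51) did not pass, nor did miR-58-3p (1.11), miR-70-3p (−0.9998), miR-48-5p (1.09) and miR-1-3p (−0.36) under the authors' scaling. In the mir-35 family 2 of 8 members rose (2 when adjusted over the list alone, and 7 with library medians, while 1 fell under the 3 other scalings), miR-38-3p and, chosen after its value was seen, miR-42-3p (1.53 ± 0.44), at a list median of 1.49 against 0.25 for the other microRNAs (camera, limma, adjusted p = 0.116). In the mir-58 family 2 of 7 members rose (2 when adjusted over the list alone), with miR-2209c-3p at 3.20 ± 0.76 and miR-2209a-3p, again chosen after its value was seen, at 1.79 ± 0.56. miR-63-3p of the mir-64 list (2.00 ± 0.42) and miR-72-5p of the mir-72 family (1.73 ± 0.52) were the single members of their lists that rose. Of the 61 passenger strands, 6 rose and 3 fell (also 6 and 3 when adjusted over the list alone). In the let-7, mir-51, mir-2, mir-44, nervous-system, muscle, intestine, glia and mirtron lists, 0 members passed under the authors' scaling. miR-237-5p of the lin-4 family (−1.26) did not pass either, but did when adjusted over the list alone. Under all 4 other scalings miR-246-3p was called higher, and miR-70-3p, miR-237-5p, let-7-5p, miR-241-5p and the mirtron miR-1020-3p were called lower. With TMM and library medians 1 member each of the let-7, mirtron and nervous-system lists rose.

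The split of calls in the mutants depended on the scaling. The median change was 0.28, and it moved by −0.53 with equal totals, −0.61 with equal totals over the less abundant microRNAs, −0.25 with the trimmed mean of M-values and −0.10 with library medians. These scalings called 23 higher and 48 lower, 21 higher and 49 lower, 33 higher and 31 lower, and 47 higher and 28 lower. Of the 29 microRNAs, 20 of the 21 higher and 8 of the 8 lower were called under all 4. The count was 44 without replicate 1 of the mutants at day 0, 14 without replicate 3 at day 0, 6 without replicate 3 at day 5, and 3 when the mutant groups were fitted alone. Without replicate 1 of the mutants at day 5 it was 22, with 6 higher and 16 lower, and without replicate 2 of the mutants at day 0 it was 21, with 9 higher and 12 lower. miR-2208a-5p, miR-2214-3p, miR-34-5p and miR-230-5p were called whichever library was left out, and the other 14 of the 18 named microRNAs past the threshold lost the call at least once.

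The age changes of the 2 strains, which share no libraries, were compared across the 211 microRNAs other than mir-71. Pearson's r was 0.851 and Spearman's rho 0.830, across microRNAs, which are not independent replicates. Of the 16 and 21 microRNAs that rose in N2 and in the mutants, 11 were common to both, where independent lists would share 1.59, and of the 34 and 8 that fell, 8 were common, where independent lists would share 1.29. Both tests used the same pooled variance for each microRNA, so shared calls are likelier than these independent numbers allow for. Libraries of the 2 strains with the same replicate number also deviated alike from their group means. The correlations of these deviations were 0.247 to 0.56 at day 0 and 0.335 to 0.466 at day 5. Such shared deviations can raise Pearson's r and the number of shared calls, by an amount that was not tested. miR-38-3p, miR-34-5p, miR-2214-3p and miR-2208a-5p were among the shared rises and both arms of mir-230, miR-357-3p and miR-1817 among the shared falls, while 0 microRNAs were called in opposite directions.

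**Figure D3:**
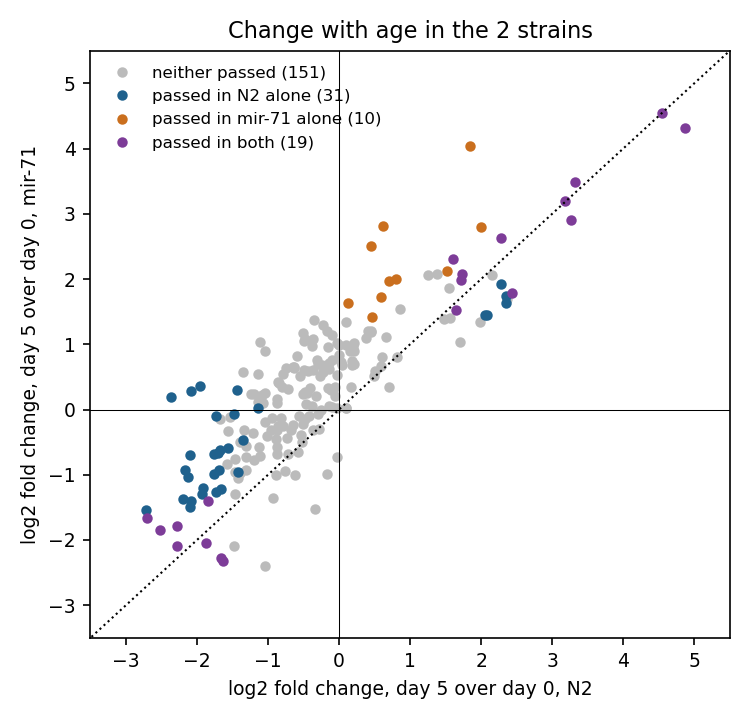
Log2 change between day 0 and day 5 in N2 (horizontal axis) and in mir-71 mutants (vertical axis) for 211 microRNAs, coloured by the strain in which each passed the limma test, with a dotted line of equal change. Of the 211 microRNAs, 177 had the larger value in the mutants and so lay above the line, and 19 passed the test in both strains.

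At day 0, limma called 0 of 211 microRNAs between mutants and N2, and 5 had an unadjusted p under 0.05. The smallest adjusted p was 0.903, and the median log2 difference was 0.27 with a median SE of 0.53. lin-4-5p (0.17), miR-34-5p (0.40), miR-238-3p (0.01), miR-239a-3p (0.33), miR-239b-5p (7 reads against 1, ratio 5.88, counting interval 0.755 to 265), miR-246-3p (0.60), miR-80-3p (0.26) and miR-228-5p (0.07) of the lifespan list did not pass. Neither did miR-58-3p (0.42 ± 0.54), miR-70-3p (0.46 ± 0.59), miR-48-5p (0.05 ± 0.49) and miR-1-3p (0.57 ± 0.65). The median moved by −0.13 with equal totals and with equal totals over the less abundant microRNAs, by −0.28 with the trimmed mean of M-values and by −0.20 with library medians, and 0 microRNAs were called under each. In each of the 16 lists 0 members passed, also when adjusted over the list alone, and camera called 0 lists, with mirtrons (median 0.99) and the mir-51 family (median −0.07) at the lowest adjusted p, 0.352.

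At day 5, 48 of 211 microRNAs were higher in mir-71 mutants than in N2 and 0 were lower. limma gave an unadjusted p under 0.05 for 95, each higher in the mutants. The largest difference was that of lsy-6, the taste-neuron microRNA, at 36.6 ± 15.4 normalised reads in mutants and 3.71 ± 3.25 in N2 (SD, n = 3 in each group), a log2 difference of 3.35 ± 0.71 (SE, limma adjusted p = 0.00953). The N2 libraries at day 5 had 0, 5.06 and 6.05 normalised reads of lsy-6, so the size of this difference depends on the added 1. At day 0 its log2 difference between mutants and N2 was 0.99, which was not called. The abundant miR-85-3p stood at 29727 ± 16113 and 5293 ± 1892 reads (2.43 ± 0.50, adjusted p = 0.00923). miR-793, a let-7 relative also on the nervous-system list, stood at 953 ± 508 and 165 ± 16.6 reads (2.403 ± 0.53, adjusted p = 0.0113). miR-785 (2.64), miR-239a-5p (2.53), miR-1821 (2.41), miR-784-5p (2.37) and miR-795-3p (2.34) completed the 8 largest.

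Of the 5 nervous-system microRNAs, 4 were higher in mutants at day 5 (5 when adjusted over the list alone), namely lsy-6, miR-793 and, chosen after their values were seen, miR-124-3p (1.86 ± 0.55) and miR-790-5p (1.47 ± 0.42). Under the 4 other scalings 2 were called, lsy-6 and miR-793. The count was 0 without replicate 1 of the mutants at day 5 and 1 without replicate 2 of N2 at day 5. The list's median was 1.86 against 0.95 for the other microRNAs, positive under each scaling, and camera called it (limma, adjusted p = 0.0319), with an adjusted p of 0.835 with an estimated correlation. Among libraries left out in turn, that call was lost without replicate 3 of N2 at day 5 (adjusted p = 0.0819) and without replicate 2 of the mutants at day 5 (adjusted p = 0.0687). In the mir-64 list, mir-229, mir-64, mir-65 and mir-66 lie in an intron of gcn-1 on chromosome III and mir-63 lies on chromosome X. Of these 5 members 4 were higher (5 when adjusted over the list alone), from miR-66-5p (1.93 ± 0.60) down to miR-64-5p (0.91), which did not pass alone. Under the other scalings 1 member or 0 passed. In the let-7 family 3 of 7 were higher (4 when adjusted over the list alone), between miR-793 and let-7-5p (0.26), which did not pass. Of this list miR-793 alone was called higher under all 4 other scalings. The lifespan list had 2 of 8 higher (7 when adjusted over the list alone), miR-239b-5p (3.24 ± 0.81) at a mean of 1.27 ± 1.30 reads in N2, and lin-4-5p (1.14 ± 0.39, adjusted p = 0.0482), which passed under 0 of the 4 other scalings. Its other members, miR-34-5p (1.11), miR-238-3p (0.96), miR-239a-3p (0.65), miR-246-3p (1.28), miR-80-3p (1.17) and the glial miR-228-5p (1.13), did not pass, nor did miR-58-3p (0.88), miR-70-3p (0.35), miR-48-5p and miR-1-3p (1.42).

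Single members were higher in the mir-51 family (miR-55-3p, 1.23, at a list median of 0.66 that was negative under the 4 other scalings), the lin-4 family (lin-4-5p), the mir-2 family (miR-797-5p, 1.82), the mir-72 family (miR-74-3p, 1.26, chosen after its value was seen) and the mirtrons (miR-62, 2.23), as was the intestinal marker miR-60-3p (1.5005). Of these, miR-62 alone was called higher under all 4 other scalings. Adjusted over the list alone, 2 members passed in the mir-51 and mir-72 families and 1 in the lin-4 and mir-2 families and the mirtrons. The muscle, intestine and glia lists hold 1 member each, so for them this is the unadjusted limma p, which was under 0.05 for each. The same held for 95 of the 211 microRNAs. In the mir-35, mir-44 and mir-58 families 0 members passed under the authors' scaling. camera placed the mir-35 family below the other microRNAs at day 5 (adjusted p = 0.00315, and 0.835 with an estimated correlation), although its median was 0.16 against 1.01 for the others under the authors' scaling and between −0.51 and −0.78 under the 4 other scalings. The passenger strands, of which 8 of 61 were higher (4 when adjusted over the list alone), were likewise below the others (median 0.84 against 1.04, and −0.07 with the trimmed mean of M-values, adjusted p = 0.0319, and 0.835 with an estimated correlation). The passenger call was lost with equal totals (0.0974), with the trimmed mean of M-values (0.152), without replicate 1 of N2 at day 5 (0.114) and without replicate 2 of the mutants at day 5 (0.0687).

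The difference at day 5 was a shift of most microRNAs under the authors' scaling, with a median of 0.98, and its size and the split of calls depended on the scaling. Equal totals moved the median by −0.67, equal totals over the less abundant microRNAs by −0.69, the trimmed mean of M-values by −0.94 and library medians by −0.84, and the calls became 20 higher and 5 lower, 17 and 5, 14 and 11, and 18 and 13. Under all 4 other scalings 14 of the 48 were called higher, among them lsy-6, miR-785, miR-85-3p, miR-1821, miR-793, miR-784-5p and miR-795-3p, and 5 were called lower, among them miR-36-5p, miR-41-5p and miR-44-5p. Relative to the median difference lsy-6 had 2.37, miR-85-3p 1.44 and miR-1821 1.43. The count was 1, miR-1821, without replicate 1 of the mutants at day 5, 3 without replicate 2 of N2 at day 5, 6 without replicate 1 of N2 at day 5, 25 without replicate 3 of the mutants at day 5 and 75 without replicate 2 of the mutants at day 0.

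**Figure D4:**
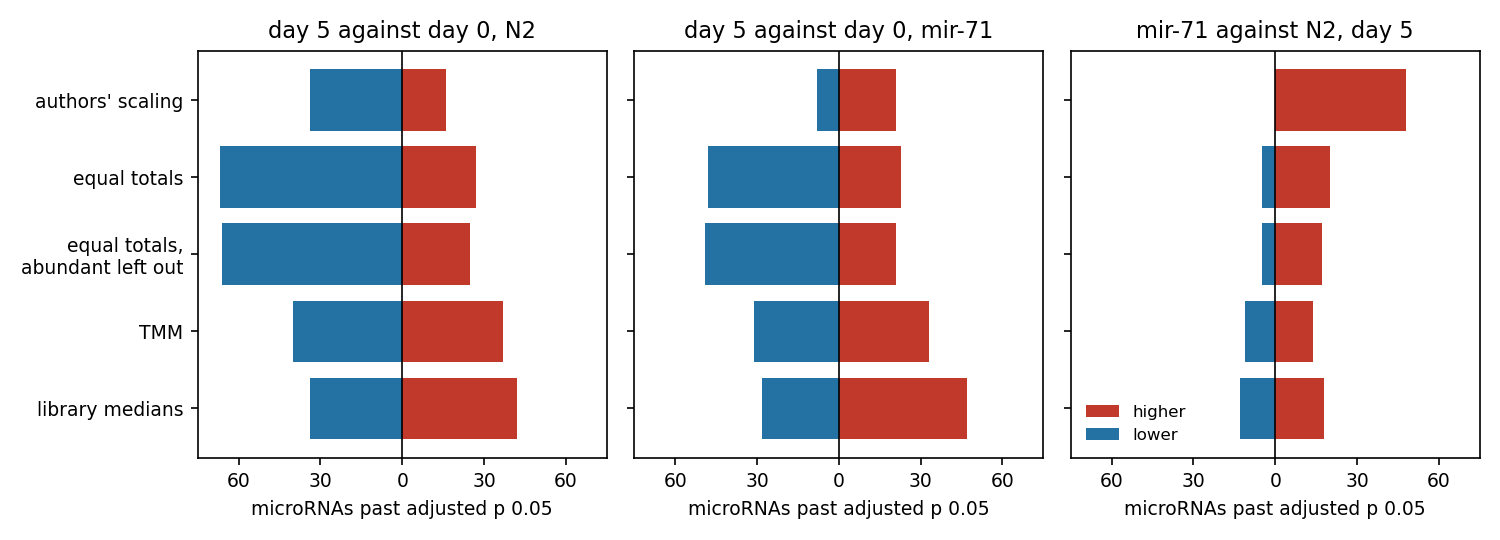
Numbers of microRNAs past the limma test, higher to the right and lower to the left of 0, in 3 comparisons under the authors' scaling and 4 others. For mutants against N2 at day 5 the counts were 48 higher and 0 lower under the authors' scaling and 14 higher and 11 lower with the trimmed mean of M-values (TMM).

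The difference between the age effects, that of the mutants minus that of N2, was 0.70 in the median over 211 microRNAs. limma called 0 of them, and 25, each with a larger value in the mutants, had an unadjusted p under 0.05, the smallest adjusted p being 0.398. The median moved by −0.54 with equal totals, −0.55 with equal totals over the less abundant microRNAs, −0.64 with the trimmed mean of M-values and −0.64 with library medians. For the nervous-system list the median difference was 1.70 against 0.68 for the other microRNAs, from lsy-6 (2.36) to miR-791-3p of carbon dioxide-sensing neurons (1.35), and camera called it higher (limma, adjusted p = 0.00687, and 0.735 with an estimated correlation). For the mir-35 family it was −0.14 against 0.71, and camera called it lower than the others (adjusted p = 0.000661, and 0.735 with an estimated correlation), a call lost without replicate 1 of the mutants at day 0 (0.0542). lin-4-5p (0.97), let-7-5p (0.44) and miR-34-5p, which rose in both strains, were among the microRNAs whose age effects were not shown to differ.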

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

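All tests of explanations in this section and in the other observations were chosen only after the results were seen, while the counts over splits of the libraries were planned before for microRNAs and lists and were added later for arm ratios.

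The age effect of the mir-35 family differed between the strains relative to the other microRNAs, with a camera adjusted p of 0.000661 (limma), and this difference between groups is what drew attention to it. The median difference was −0.14 for the family and 0.71 for the others. The adjusted p was 0.735 with an estimated correlation and 0.0542 without replicate 1 of the mutants at day 0. The nervous-system list differed in the other direction, with a camera adjusted p of 0.00687, 0.735 with an estimated correlation. fry, which tests a list against no change and not against the other microRNAs, gave an adjusted p of 0.869 for the mir-35 family and 0.137 for the nervous-system list. Of 100 splits of the libraries, 20 gave at least the 2 lists called in the real one, and the highest of the others gave 4, so chance was not excluded for these 2 differences. For single microRNAs the difference between age effects gave 0 calls in limma (25 at an unadjusted p under 0.05), 100 of 100 splits gave at least as many, and the highest of the others gave 50. With a real count of 0 each split was bound to give at least as many.

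At day 5, 48 microRNAs were higher in the mutants and 0 lower. If 1 scale factor per library were the whole cause, calls in that direction would be lost under other scalings. Under the trimmed mean of M-values, which kept the fewest, 14 of the 48 were still called higher, which argues against it for those 14. The same scaling called 11 lower and took the median difference from 0.98 to 0.04. For the one-sided shift, a scale factor therefore stays open. Without the mutant library with the highest total, replicate 1 at day 5, the median difference over microRNAs was 0.68, against 0.98 with it. The count without that library was 1. A different statistic, the difference between the library medians of the strains, had an SE of 0.413 without it, with replicate numbers ignored. Against that spread, a shift carried by that library and one shared by the group cannot be told apart. The library medians of the normalised values at day 5 gave an exact permutation p of 0.2 between strains, with 0.1 the smallest possible, so this test could not reach 0.05 and a difference in overall microRNA level between the strains stays open. Matched by replicate number, the library medians of the mutants were higher by 1.56, 0.58 and 0.67 for replicates 1, 2 and 3, and with the numbers as a replicate block 95 microRNAs were called higher and 1 lower, 96 in all, although no label says that the numbers pair libraries.

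With 3 libraries against 3 there are 10 splits, so the share of splits with a result as large cannot go below 0.1. Where the real result was 0, each split counts as at least as large, so those shares were fixed in advance. For microRNAs called, 1 of the 10 splits gave as many as the real one for age in N2 (50, highest other 0), 1 for age in the mutants (29, highest other 0) and 1 between strains at day 5 (48, highest other 0). Between strains at day 0 it was 10 of 10 (0, highest other 17). The split with 17 set replicate 1 of N2 and replicates 1 and 3 of the mutants against the rest, a structure among the day 0 libraries that does not follow the strain. It follows the level left by the authors' scaling: the log2 library medians were 7.52, 7.80 and 7.43 in these 3 and 6.81, 6.75 and 6.90 in the rest. For lists called, the numbers were 8 of 10 for age in N2 (1, highest other 3), 10 for age in the mutants (0, highest other 3), 10 at day 0 (0, highest other 2) and 1 at day 5 (3, highest other 2).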

How the results depend on the processing

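Arm ratios, list tests under other scalings and the fit without miR-45-3p were added after the data were seen. Over 81 named results and their alternatives, 2082 values were obtained: 1865 kept direction and side of the threshold, 132 lost the threshold, 50 gained it and 35 turned in sign, 0 of the last among the 49 past the threshold. Of these 49, 28 kept their call under each alternative fixed beforehand other than leaving out a library. Alternatives on recovered reads with edgeR and DESeq2 were not run, and dropping the filter removed nothing and so tested nothing. In simulation at this group size, 16.8% of log2 changes of 1, 58.9% of changes of 2 and 87.7% of changes of 3 were found, and the effect of depth on these shares was not tested.

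Counts of called microRNAs are given for age in N2 (50), age in the mutants (29) and strain at day 5 (48). They were 26 and 19 for both age comparisons at a mean of at least 50, where fewer microRNAs were tested. They were 94, 71 and 25 with equal totals, 91, 70 and 22 with equal totals over the less abundant microRNAs, 77, 64 and 25 with the trimmed mean of M-values (TMM) and 76, 75 and 31 with library medians. The cause was not tested. Fits of the compared groups alone gave 79 and 3 for the age comparisons, where the spread of the other groups was not used. Lists called by camera went from 1 to 0 for age in N2, from 3 to 0 for strain at day 5 and from 2 to 0 for the difference between age effects with an estimated correlation. The estimates were 0.918 for the mir-35 list, 0.358 for the nervous-system list and 0.502 for the passenger strands, far above the preset 0.01. fry called 0, 5 and 0 for the same comparisons, and equal totals called 1 instead of 0 for age in the mutants. fry tests a list against no change, and for strain at day 5 its direction was up for every list tested. The median difference there was 0.98, so its 5 calls need not be particular to these lists. For the other fry counts and for equal totals the cause was not tested.

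Leaving out 1 library at a time, where a group left with 2 libraries shares the pooled spread, gave 10 to 67 called microRNAs for age in N2, 6 to 44 for age in the mutants, 0 to 0 for strain at day 0, 1 to 75 for strain at day 5 and 0 to 0 for the difference between age effects. Lists called were 1 to 1, 0 to 1, 0 to 0, 1 to 5 and 1 to 3 in that order, and Pearson's r between the age effects was 0.812 to 0.862. Members called in the mir-35 list were 0 to 7 for age in N2 and 0 to 7 for age in the mutants, members that fell in the let-7 list 0 to 4 for age in N2, and members higher at day 5 were 0 to 4 in each of the nervous-system, mir-64 and let-7 lists. Of the passenger strands, 1 to 8 rose and 1 to 7 fell for age in the mutants, and 0 to 14 were higher at day 5.

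No label says that replicate numbers pair libraries, and 13 of the 18 pairs with the same number had a correlation over 0.1 in their deviations from the group means, the lowest of all being −0.169. Between the strains within a day all 3 pairs did, at 0.335 to 0.466 for day 5 and 0.247 to 0.56 for day 0. Treated as a block, they gave 86, 67 and 96 called microRNAs for age in N2, age in the mutants and strain at day 5, 0 for strain at day 0 and 0 for the difference between age effects. The block gave 1 called list instead of 0 for age in the mutants and an adjusted p of 0.0566 for the nervous-system list at day 5, and 11 of the 12 libraries correlated best with a library of their own number. The exact tests of totals ignored the numbers, and within numbers 1, 2 and 3 the totals differed by 1996805, 593984 and 509520 for age in the mutants, 2895396, 533998 and 463587 for strain at day 5, 681938, −313620 and 414547 for strain at day 0 and −216653, −253634 and 460479 for age in N2.

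Named microRNAs that turned in sign had not passed the threshold, and for those the cause was not tested. For age in N2, miR-71-5p had 0.0097 (TMM) and 0.13 (library medians), miR-80-3p 0.18 and 0.30, miR-239a-3p 0.12 (library medians) and miR-71-3p −0.0082 with equal totals over the less abundant. For age in the mutants, lin-4-5p had −0.44, −0.53, −0.14 and −0.0097 with equal totals, equal totals over the less abundant, TMM and library medians, and miR-228-5p −0.0308 and −0.11 with equal totals of both kinds. For strain at day 5 under the same 4 scalings, miR-239a-3p had −0.0188, −0.036, −0.28 and −0.19 and miR-70-3p −0.32, −0.34, −0.59 and −0.49, and under TMM miR-58-3p had −0.0644 and miR-48-5p −0.19 (−0.0787 with library medians). Leaving out a library turned miR-71-3p for age in N2 (−0.37 to 0.30), lin-4-5p (−0.17 to 0.39), miR-239a-3p (−0.69 to 0.27) and miR-1-3p (−1.16 to 0.28) for age in the mutants, and miR-70-3p for strain at day 5 (−0.25 to 0.93).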

Other observations

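Both arms of a precursor were compared within each library, a ratio from which a scale factor of the library drops out apart from the 1 added to each value, for 45 precursors whose weaker arm had a mean of at least 20. With age in N2 the share of the weaker arm fell for 9 precursors and rose for 2, and in the mutants it also fell for 9 and rose for 2 (limma). The falls common to both strains were those of miR-36, miR-39 and miR-40 of the mir-35 family and of miR-51, miR-54 and miR-73, and the rises were those of miR-239a and miR-243. The miR-39 passenger strand made up 0.418% ± 0.212 of both arms in N2 at day 0 and 0.0386% ± 0.0132 at day 5 (SD, n = 3 in each group), a log2 change of −3.32 ± 0.48, and the change in the mutants was −4.33 ± 0.48. miR-239a-5p went from 7.73% ± 5.17 to 31.4% ± 15.7 in N2 (2.41 ± 0.66) and from 18.0% ± 7.77 to 61.3% ± 8.51 in the mutants (2.90 ± 0.66), so that in aged mutants it was the more abundant arm. miR-243-5p, whose sister strand is known to enter the Argonaute RDE-1, went from 1.14% ± 1.18 to 6.88% ± 0.82 in N2. Across the 45 precursors, which are not independent replicates, Pearson's r between the 2 age changes was 0.921. Deviations shared by libraries of the same replicate number could raise this value, which was not tested.

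Between strains, limma called 0 arm ratios at day 0 (1 at an unadjusted p under 0.05), 1 at day 5, miR-84 (−1.69 ± 0.37, adjusted p = 0.0221), and 0 for the difference between the age effects (0 at an unadjusted p under 0.05). With a weaker-arm mean of at least 100, the age comparisons called 1 precursor each. For age in N2 the count was 5 without replicate 1 of N2 at day 0 and 6 without replicate 2 of N2 at day 0 or at day 5. For age in the mutants it was 6 without replicate 3 of N2 at day 0, without replicate 2 of N2 at day 5 and without replicate 2 or 3 of the mutants at day 5. It was 7 without replicate 1 or 2 of N2 at day 0, replicate 3 of the mutants at day 0 or replicate 1 of the mutants at day 5. The miR-84 call was lost without replicate 1 or 2 of N2 at day 5 or any of the 3 mutant libraries at day 5, where the count was 0, and the count was 2 without replicate 2 of the mutants at day 0. As a replicate block, the counts were 12 and 13 for age and 0, 1 and 0 for the others. As many arm ratios as in the real split were found in 1 of 10 splits for age in N2 (11, highest other 0), in 1 of 10 for age in the mutants (11, highest other 0), in 10 of 10 at day 0 (0, highest other 4) and in 1 of 10 at day 5 (1, highest other 0), where the share cannot go below 0.1. For the difference between age effects it was 100 of 100 splits (0, highest other 4). Where the real count was 0, here and at day 0, each split was bound to give at least as many.

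In the mir-35 family, 4 of the 8 listed members rose with age in N2, and the list, called by camera, had an adjusted p of 0.985 with an estimated correlation. If reads shared between near-identical members were the whole cause, the 7 guide strands on the list would move together. The list leaves out the scarce miR-41-3p. Of the 7, 3 differed from the family mean, miR-38-3p by 2.30, miR-36-3p by −0.68 and miR-40-3p by −0.77. This argues against that cause for miR-38-3p. The family mean includes miR-38-3p, which lowers the deviations of the others. Those of miR-36-3p and miR-40-3p therefore do not show that the remaining members moved apart. If more of the day 0 source were the whole cause, arm ratios would stay, but over the 4 precursors with both arms the median change was −3.08 (median SE 0.647) in N2 and −3.61 in the mutants. The ratio fell for miR-36, miR-39 and miR-40, which argues against that cause alone for these 3. Their weaker arms were scarce, with means of 30, 89 and 39 over the 12 libraries. Guide reads shared with miR-35 would also lower these ratios and were not excluded for these 3. For miR-35, whose 2 arms both rose in N2, the ratio change was 0.29 ± 0.72, as that hypothesis predicts, so for miR-35 that cause stays open. For the other 3, guide strands that outlast their passenger strands remain a candidate explanation that was not tested. A source of mir-35 family RNA absent at day 0 also stays open. The arm ratio of such a source is not known, so this test cannot address it. Age and time on the inhibitor of DNA synthesis went together in both strains, so their effects cannot be separated here.

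A total of 895 miR-71-5p reads were found in the 6 mutant libraries (58, 100, 103, 84, 364 and 186), although the gene is deleted. If these reads were carried over from the N2 libraries, miR-71-3p would be carried over at the N2 ratio, with 2.19 reads expected and a probability of 0.112 for the 0 reads found. Carry-over and another source of these reads cannot be told apart by this test.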
